A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

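Ribosome footprints and mRNA of yeast were sequenced from wild type and *tif3*Δ cells at 37 °C (experiment 1) and 15 °C (experiment 2), in 16 libraries. Groups were taken from the sample labels, 8 groups of 2. The submitters' processing notes list CASAVA 1.8, Bowtie2 2.0.6, TopHat2 2.0.7, DESeq and the build sacCer2, without roles or order. Each deposited table holds, per gene, a log2 normalised read value for wild type and *tif3*Δ in footprints and mRNA, and the authors' log2 differences for footprints, mRNA and TE. How the authors combined the 2 libraries of a group is not given in the sources used here, and no column holds a single library, a count or a p-value.

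The deposited log2 columns were checked against each other. Footprint and mRNA differences equal *tif3*Δ minus wild type within 0.0098 and 0.0991 at 37 °C and 0.0546 and 0.0996 at 15 °C, the size of the rounding of the group values, and the TE difference is the footprint minus the mRNA difference. Because mRNA enters both, differences in TE and mRNA tend to run in opposite directions by construction. Genes without a footprint in a group (22 in wild type and 23 in *tif3*Δ at 37 °C, 29 and 65 at 15 °C) carry log2 values far below 0, and their footprint and TE differences were not used as folds. Where 1 group had footprints, a bound was computed against a floor of 3 footprints over the group, which covers counting error only.

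The lowest footprint values fall on steps, the value of 1 footprint in the group. The steps were 0.735 normalised units in wild type and 1.082 in *tif3*Δ at 37 °C, and 0.728 and 2.182 at 15 °C. Of the values up to 6 steps, 97.5%, 100.0%, 85.7% and 84.6% lay within 0.15 steps of a whole number. The wild-type footprints were therefore 1.47 times as deep as those of *tif3*Δ at 37 °C and 3.00 times at 15 °C, and approximate footprint numbers in the text come from these steps. To find the *tif3*Δ steps, the wild-type value, given to 2 decimals, plus the authors' difference was used, since the group values of *tif3*Δ footprints at 15 °C are mostly rounded to 1 decimal. The footprint numbers in the text are the group values as deposited over these steps, so those of *tif3*Δ at 15 °C carry that rounding. Wild-type mRNA is rounded to 1 decimal as well, too few for this, and the shares of whole values show that the 15 °C steps fit less closely than those at 37 °C. Rounding and the lack of replicates limit the precision of every value, and values of genes with few footprints are uncertain. Rows with the same values in every column (34 at 37 °C, 21 at 15 °C) are mostly copies of repeated genes that share reads, as ribosomal protein paralogs can too.

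The planned tests, a count model of the TE interaction with list tests on the same fit, or a linear model of log values, need single libraries and could not be run. They were replaced by descriptions. Genes needed a mean normalised value of 10 or more over the 2 genotypes in both footprints and mRNA (5197 genes with a TE difference at 37 °C, 5012 at 15 °C, 4999 in both). Genes at least 1.5-fold apart were counted, a size chosen after the tables were seen to hold no replicates. The rule for named genes was fixed before the data were examined: *TIF3*, then the 10 highest and 10 lowest genes in TE, 8 and 8 in mRNA and 5 and 5 in footprints among genes with a mean of 32 or more in both library types, then members of the lists. Its conditions on adjusted p-values and replicate signs could not be applied. *YEF3*, *PMA1* as an example of depth, list members other than those of the size rule, and the wild-type examples were chosen after their values were seen.

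The fixed lists were cytosolic and mitochondrial ribosomal proteins, initiation factors, elongation and termination factors, ribosome biogenesis, glycolysis and fermentation, heat shock and chaperones, cold-induced genes, the general stress response, amino acid synthesis, oxidative phosphorylation, proteasome, ergosterol synthesis, cell wall, pheromone response, mRNAs with upstream open reading frames, genes specific to a cells, to α cells and to sporulating cells, and strain markers. Some members taken in by name have other functions, *RPP1* among ribosomal proteins, *RPN4* and *RPN14* in the proteasome list, *GCD10* and *GCD14* among initiation factors and *MRP8* among mitochondrial ribosomal proteins, so these 4 lists were also run without them, an alternative added after the data were examined. The highest and lowest 10% of the genes by coding length, start-region folding, and wild-type TE and mRNA at the other temperature were added as planned. For each list the median was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean mRNA expression; percentiles under 2.5 or over 97.5 are called outside the middle 95%. With 20 lists (19 at 15 °C), 1 would be expected outside by chance if genes varied independently. Members that vary together or share reads can raise this number. No percentile was given to the lists by mRNA level or to lists under 3 genes. An alternative matched coding length as well, in 10 by 10 bins. TE differences for 5197 genes were also simulated, with independent values and members picked at random. Lists of 40 genes shifted by 0.25 on the log2 scale lay outside the middle 95% in 66.7% of 60 runs, and unshifted lists in 5.0%. Unshifted lists of 130 genes lay outside in 8.3%. Such draws cannot show how often lists of genes that vary together fall outside.

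Coding lengths, GC content and start regions came from the R64 reference, which may not be the build of the submitters' notes, so no coordinates are printed; 5328 of 5330 and 5188 of 5190 gene identifiers matched it. Gene names are the tables' own, or those of R64 for the 701 and 653 genes without one, including 1 name that had become a date. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88, matplotlib 3.10.9 and RNAfold 2.7.2 were used, the last on 60 nt before and 15 nt from the start codon. Hydrophobic segments were counted as windows of 19 residues with a mean hydropathy above 1.8. Alternatives were no filter, a filter of 64, the ribosomal protein genes left out, a 2-fold size, the mating and histone genes left out, length relations given GC content or mRNA level, and length-matched lists. The relations with GC content, the hydrophobic segments and the alternatives from the 2-fold size on were chosen after the data were examined. Further gene properties, other segment counts and a rank regression at each temperature were looked at while the data were explored and are not reported.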

Results

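Ribosome-protected mRNA fragments (footprints) and mRNA were sequenced from budding yeast, *Saccharomyces cerevisiae*, with and without *TIF3*, the gene of the translation initiation factor eIF4B. Cells were shifted to 37 °C in the first experiment and to 15 °C in the second. The 16 libraries form 8 groups of 2, one group for each combination of temperature, genotype (wild type or *tif3*Δ) and library type. The deposited tables hold 1 log2 normalised value per gene and group, so no difference below has a replicate check, a test or an error, and "higher" and "lower" describe the group values alone. They list 5330 genes at 37 °C and 5190 at 15 °C, 5182 of them in both. The spacing of the lowest footprint values puts the footprints assigned to listed genes at about 17500000 in wild type and 11900000 in *tif3*Δ at 37 °C, and at about 5400000 and 1800000 at 15 °C. The depth of the mRNA libraries is unknown. Translational efficiency (TE) is the footprint value over the mRNA value of a gene. The values are normalised, and the median TE difference was 0.038 at 37 °C and -0.003 at 15 °C. Higher or lower TE in *tif3*Δ is therefore relative to the other genes, and a change of translation common to all genes cannot be seen.

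*TIF3* (YPR163C) was lower in every *tif3*Δ group. At 37 °C the authors' deposited table put its mRNA 271.8-fold lower and its footprints 157.0-fold lower than in wild type, or about 34 footprints against 7827. At 15 °C the authors' deposited table gave mRNA 18.3-fold lower and footprints 43.8-fold lower, about 24 footprints against 3057. The *TIF3* mRNA left in *tif3*Δ stood at log2 3.1 at 37 °C, against 9.1 for the median gene, and at 6.4 against 7.4 at 15 °C. The source of this remaining signal, larger at 15 °C, was not tested. The gene was left out of all counts and lists below.

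The first comparison asked which mRNAs differed in TE without eIF4B at 37 °C, with the question of the series being whether long mRNAs and those with structured 5′ leaders differ most. Genes with long coding sequences had lower TE in *tif3*Δ and genes with short ones had higher TE. In the shortest 10% of the genes, with a median coding length of 357 nt, the median log2 TE difference was 0.51 and 6.7% of the genes were lower in *tif3*Δ. In the longest 10%, with a median of 3556 nt, the median was -0.55 and 92.3% were lower. Across 5195 genes the Spearman correlation of the TE difference with coding length was -0.650. Both parts of TE contributed, since footprint differences correlated negatively with length (rho = -0.322) and mRNA differences positively (rho = 0.341). These correlations are across genes, which are not independent replicates, and 30 such relations were computed (5 gene properties, 3 differences, 2 temperatures).

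**Figure D1:**
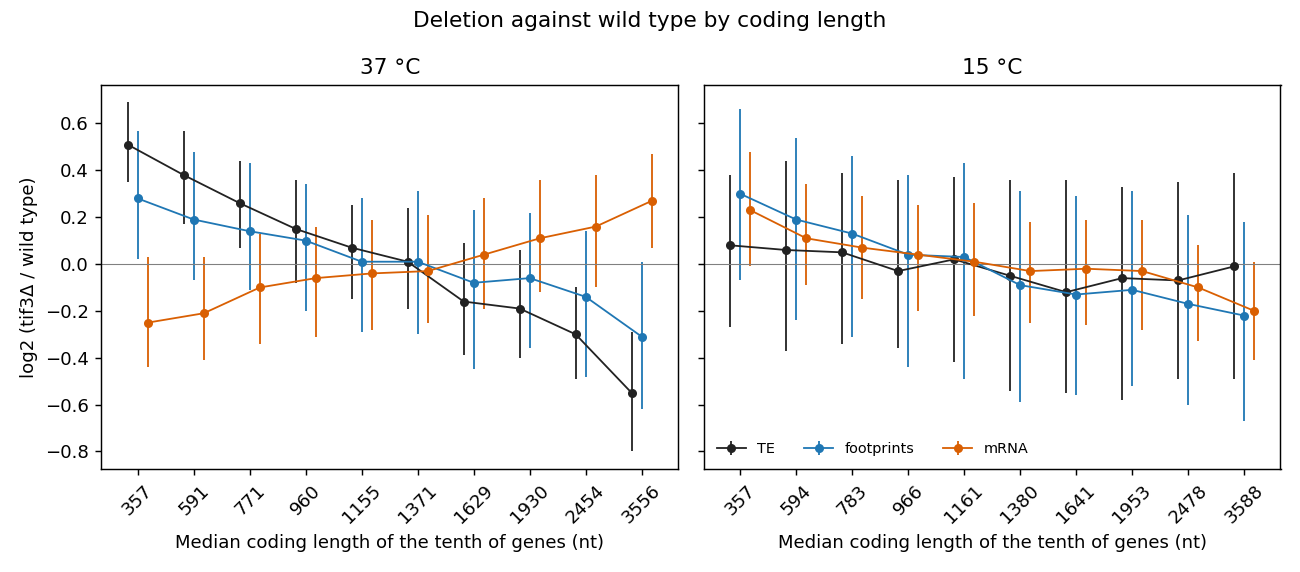
Median log2 difference of *tif3*Δ over wild type (y axis) in TE, footprints and mRNA for 10 groups of genes ordered by coding length (x axis, median length in nt), at 37 °C (left) and 15 °C (right). Bars span the quartiles over genes, not replicate error. TE medians run from 0.51 to -0.55 at 37 °C and from 0.08 to -0.01 at 15 °C.

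At 37 °C, 537 of 5197 genes had TE at least 1.5-fold higher in *tif3*Δ and 579 had TE at least 1.5-fold lower. Among genes with a mean normalised value of 32 or more, the lowest was *MMS1* (YPR164W), a subunit of a ubiquitin ligase and the direct neighbour of *TIF3*, at 11.7-fold lower TE and 2.47-fold higher mRNA in the authors' deposited table. The authors' deposited table next listed *ATF1*, an alcohol acetyltransferase, at 8.35-fold lower, the mitochondrial oxodicarboxylate carrier *ODC2* at 6.03-fold lower and *HBT1* at 5.71-fold lower. *DUR1,2*, *PCL5*, *HER1*, *URA2*, *PEP1* and *ADH4* followed, between 4.89-fold and 4.03-fold lower in the authors' deposited table. *URA2*, the large first enzyme of pyrimidine synthesis, rested on about 37230 wild-type footprints, and *PCL5* on about 98. On the higher side, the authors' deposited table gave 9.02-fold for YMR001C-A, 5.77-fold for *KDX1*, 4.91-fold for *AAD14*, 4.83-fold for *ECM10*, 4.74-fold for the zinc transporter *ZRT1* and 4.43-fold for the α-factor receptor *STE2*. *IRC18*, *ECM12*, *FIG1* and YDR124W, at 4.27-fold to 3.51-fold, completed the 10 highest in the authors' deposited table. Apart from *ZRT1*, each of these 10 had about 42 or fewer wild-type footprints, so their folds carry a wide counting error.

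Among the gene groups at 37 °C, TE was higher for 134 of 135 cytosolic ribosomal protein genes, or 135 of 136 in the list as fixed, which also held *RPP1* of RNase P, with a median log2 difference of 0.46 that lay above all but a few of 10000 random lists matched on mean expression (percentile 100.0). These genes are short, and among random lists matched on coding length as well the percentile was 87.5. Their footprint median was 0.08 (91 of 136 higher, percentile 99.9, or 63.6 with length matched) and their mRNA median -0.35. The 38 oxidative phosphorylation genes had a TE median of 0.44 (28 higher, percentile 100.0, or 95.7 with length matched), and 36 of them had more footprints, with a median of 0.74. *COX9*, a cytochrome c oxidase subunit, had 2.22-fold higher TE and 2.20-fold more footprints in the authors' deposited table. Genes of the proteasome list were higher in 27 of 34 cases (26 of 32 without the regulator *RPN4* and the assembly chaperone *RPN14*), with a median of 0.20 (percentile 100.0, or 99.2 with length matched), at a footprint median of 0.05 (20 of 34 higher, percentile 96.4). The 14 cold-induced genes had a footprint median of -0.03 (7 higher and 7 lower, percentile 43.0). In TE 9 of them were lower and 5 higher (median -0.40, percentile 0.5). In the authors' deposited table the cell wall mannoprotein *TIR1* was 2.13-fold lower and the nucleolin *NSR1* 1.98-fold lower, while the thioredoxin *TRX2* and *HSP12* were higher, with log2 TE differences of 0.55 and 0.43. Footprint medians were -0.33 for the cell wall list (percentile 0.7) and -0.06 for the mRNAs with known upstream open reading frames (percentile 41.2). The latter had an mRNA median of 0.23 (10 of 13 higher, percentile 96.4). In TE the cell wall list (34 genes, median -0.22) and the mRNAs with known upstream open reading frames (13 genes, median -0.30) stood at percentiles 8.8 and 4.1, and at 1.0 and 2.4 with length matched. In the latter list *GCN4*, the activator of amino acid synthesis, was 1.67-fold lower and the cyclin *CLN3* 2.21-fold lower in the authors' deposited table.

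Of the 28 genes of the translation initiation factor list, 16 had lower and 12 higher TE at 37 °C (median -0.21, percentile 31.3). Without *GCD10* and *GCD14*, which encode a tRNA methyltransferase, 16 were lower and 10 higher. In the authors' deposited table both eIF4G genes were lower, *TIF4631* by 2.02-fold and *TIF4632* by 1.82-fold, as were *RPG1* and *NIP1* of eIF3 (1.67-fold and 1.64-fold) and the poly(A)-binding protein gene *PAB1* (1.66-fold). The short genes *TIF11* (eIF1A) and *SUI1* (eIF1) were 2.05-fold and 1.59-fold higher in the authors' deposited table. TE medians of the other fixed lists at 37 °C were 0.27 for mitochondrial ribosomal proteins, -0.14 for elongation and termination factors, -0.14 for ribosome biogenesis, 0.07 for glycolysis and fermentation, -0.12 for heat shock proteins and chaperones, -0.18 for the general stress response, -0.13 for amino acid synthesis, -0.12 for ergosterol synthesis, 0.59 for sporulation and 0.35 for the strain marker genes. None of these lay outside the middle 95% of their expression-matched random lists. The pheromone-response genes had a TE median of 0.24 (18 of 27 higher, percentile 98.0), the a-specific genes one of 1.32 (6 of 6 higher, percentile 100.0, or 1.13 with *MFA1* at its bound) and the α-specific genes one of 0.18 (3 of 4 higher, percentile 74.3). The a-specific TE median is uncertain, since some members had very low wild-type values, such as *AGA2* with about 10 wild-type footprints.

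**Figure D2:**
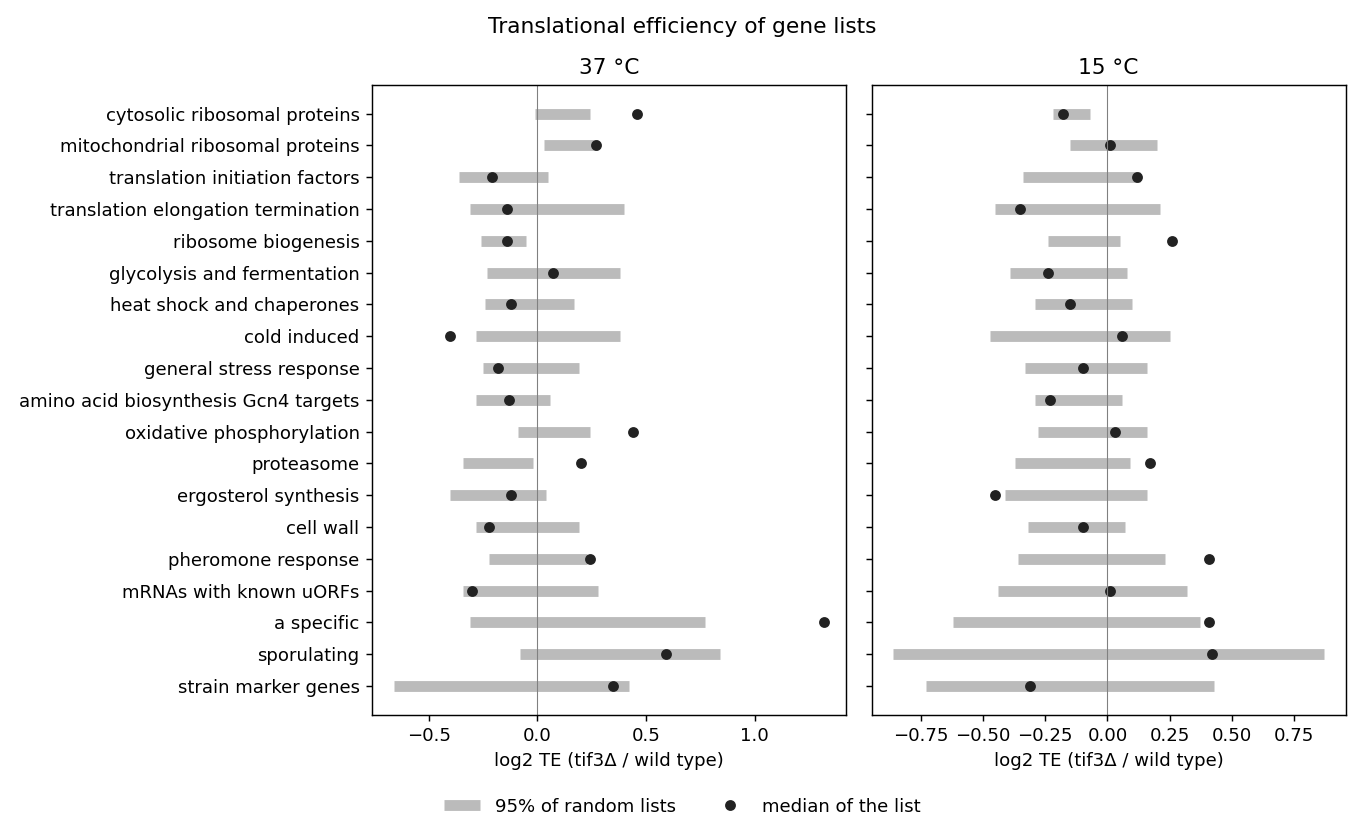
Median log2 TE difference of *tif3*Δ over wild type (points) for 19 gene lists at 37 °C (left) and 15 °C (right); grey bars hold 95% of 10000 random lists of the same size matched on mean expression, and describe these libraries only. Ribosomal protein genes stand at 0.46 at 37 °C and -0.18 at 15 °C, and ribosome biogenesis genes at -0.14 and 0.26.

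At 37 °C all 28 measured pheromone-response genes had more mRNA in *tif3*Δ, with a median log2 difference of 2.13 (4.38-fold, percentile 100.0). In the authors' deposited table *PRM6* was 39.3-fold, *AGA1* 23.3-fold, *PRM1* 16.9-fold, *SST2* 6.03-fold and *FUS1* 4.13-fold higher. The 7 genes expressed in cells of mating type a were all higher, by a median of 13.9-fold, and so were the 4 genes expressed in cells of mating type α, with a median log2 difference of 2.92; 6 and 2 of these genes, respectively, are also in the pheromone-response list. The authors' deposited table gave 14.9-fold more mRNA for the a-specific *AGA2* and 13.9-fold for *STE2*, and 14.1-fold and 13.0-fold for the α-specific *MF(ALPHA)2* and *SAG1*. Wild-type mRNA of *AGA2* and *PRM6* was low, at log2 2.9 and 3.5, against 9.0 for the median gene and a lowest listed value of 1.1. The sizes of mRNA folds from such low wild-type values are uncertain. For the a-factor gene *MFA1* no footprint was listed in wild type, about 77 were in *tif3*Δ, and footprints were at least 37.8-fold higher (floor of 3 footprints over the group). In wild type at 37 °C, mRNA of the a-specific genes stood between -0.8 (*STE6*) and -7.9 (*MFA1*) log2 units relative to the median gene, and that of the α-specific genes between 3.1 (*MF(ALPHA)1*) and -1.6 (*MF(ALPHA)2*).

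**Figure D3:**
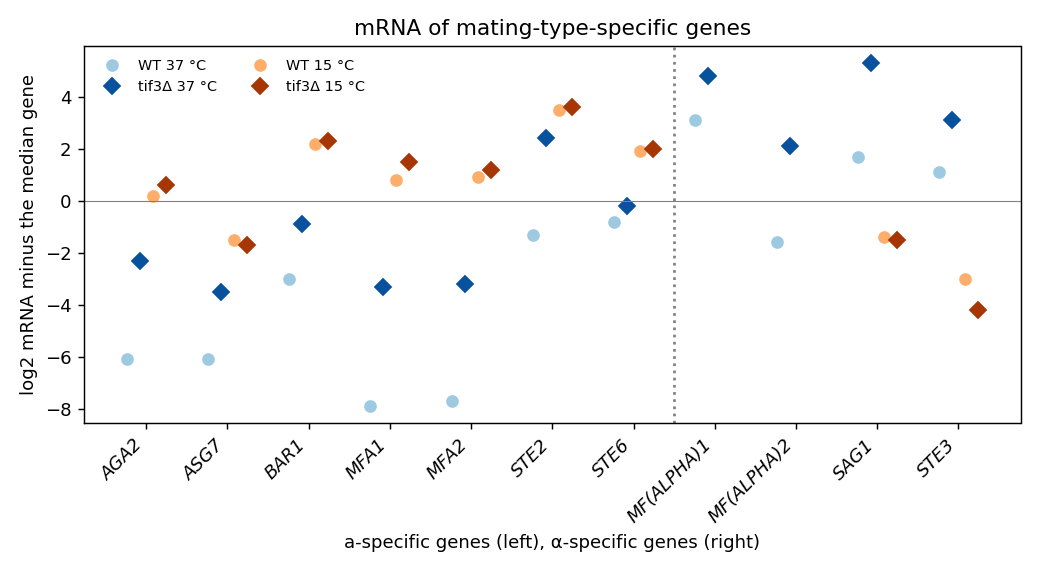
Log2 mRNA value minus that of the median gene (y axis) for 7 a-specific and 4 α-specific genes (x axis) in the 4 mRNA groups; each point is 1 group value with no error. At 37 °C *tif3*Δ lies above wild type for all 11 genes, and at 15 °C the 7 a-specific genes have a median difference of 0.14; *MF(ALPHA)1* and *MF(ALPHA)2* are not in the 15 °C table.

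Other mRNAs at 37 °C included *LEU1* of leucine synthesis, 12.5-fold higher in the authors' deposited table. The lowest mRNAs were ranked among genes with a mean normalised value of 32 or more in both library types. In the authors' deposited table they included the endonuclease gene *HO* (5.09-fold lower). The histone genes *HTA2* (4.89-fold), *HHF1* (4.88-fold), *HTB2* (3.93-fold) and *HTA1* (3.93-fold) were also among the lowest in the authors' deposited table. So were the citrate synthase *CIT2* (4.24-fold), *BNA4* (3.90-fold) and *AMF1* (3.73-fold) in the authors' deposited table. In all, 457 of 5198 genes had mRNA at least 1.5-fold higher and 461 at least 1.5-fold lower. Without the pheromone-response, mating-type and histone genes, 880 of these 918 were left. The mRNA medians were -0.35 for cytosolic ribosomal proteins (percentile 0.0, or 18.2 with length matched), 0.30 for oxidative phosphorylation (percentile 100.0) and -0.17 for ribosome biogenesis (percentile 0.0). Of the ribosome biogenesis genes, 58 of 77 were lower, and 66 of 77 had fewer footprints.

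Footprints at 37 °C were at least 1.5-fold higher for 629 genes and lower for 685. The highest and lowest footprint differences named here are among genes with a mean normalised value of 32 or more in both library types. Of these, the 5 highest in the authors' deposited table were *STE2* (61.5-fold), *AGA2* (32.6-fold), *PRM6* (29.4-fold), *PRM1* (24.9-fold) and *AGA1* (18.3-fold). All 5 belong to the mating lists. *PRM6*, *AGA2* and *STE2* had about 5, 10 and 40 wild-type footprints, so the sizes and order of their folds carry a wide counting error. Among genes above the same limit, *ICS2* (8.28-fold lower), *ATF1* (7.89-fold), *ODC2* (6.55-fold), *PLB2* (6.38-fold) and *HBT1* (6.31-fold) were lowest in the authors' deposited table.

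The second comparison asked the same at 15 °C. Here 695 of 5012 genes had TE at least 1.5-fold higher in *tif3*Δ and 946 at least 1.5-fold lower. Coding length had little relation to the TE difference (rho = -0.070 across 5010 genes). Footprint differences correlated with length as at 37 °C (rho = -0.233), but mRNA differences now ran the same way (rho = -0.290). Among genes with a mean of 32 or more, the lowest TE in the authors' deposited table was that of *LAM6*, a sterol transporter (7.96-fold lower), *SAM35* of the mitochondrial sorting machinery (7.03-fold), *MMS1* (6.85-fold), *SND2* of membrane protein targeting (5.87-fold) and the sterol acyltransferase *ARE1* (5.45-fold). *PEX2*, *STP3*, *BSP1*, the plasma membrane proton pump *PMA1* and *MET10* followed in the authors' deposited table, from 5.44-fold to 5.17-fold lower. The *PMA1* value rested on about 39184 wild-type and 3268 *tif3*Δ footprints, that of *LAM6* on about 166 and 7. Apart from *PMA1*, each of these lowest genes had about 18 or fewer *tif3*Δ footprints, so their folds carry a wide counting error. Highest TE in the authors' deposited table had the drug exporter *FLR1* (10.9-fold), YNL042W-B (8.50-fold), the glutathione transferase *GTT2* (4.02-fold), YML020W (3.43-fold), the mating gene *FIG2* (3.32-fold) and the silencing gene *SIR1* (3.27-fold). *KAR5*, *NAS2*, *MIF2* and YGL176C, from 2.92-fold to 2.70-fold, were the rest of the 10 highest in the authors' deposited table. For *FLR1* the tables hold about 6 wild-type footprints. Apart from YNL042W-B, each of these 10 highest had about 41 or fewer *tif3*Δ footprints, so their folds carry a wide counting error too.

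Ribosome biogenesis genes had higher TE in *tif3*Δ at 15 °C in 56 of 77 cases, with a median log2 difference of 0.26 (percentile 100.0) and 64 of 77 with more footprints. In the authors' deposited table *SSF1* and *NOP7* were each 2.12-fold higher and *NOP16* 2.05-fold higher. The ergosterol synthesis genes were lower in 17 of 23 cases (median -0.45, percentile 1.5), and in the authors' deposited table *NCP1* was 5.08-fold and *ERG13* 2.90-fold lower. Genes of the proteasome list had a TE median of 0.17 (21 of 34 higher, percentile 99.8), a footprint median of -0.14 (12 of 34 higher, percentile 42.9) and lower mRNA in 33 of 34 cases (median -0.33, percentile 0.0), or in 32 of 32 without *RPN4* and *RPN14*. The pheromone-response genes had a TE median of 0.41 (19 of 23 higher, percentile 100.0) at an mRNA median of 0.09, and the 7 a-specific genes one of 0.41 (percentile 98.5) at an mRNA median of 0.14. Of the α-specific genes 1 passed the filter, *STE3*, with about 41 wild-type and 2 *tif3*Δ footprints, too few for a fold. Genes of the initiation factor list had a median of 0.12 (18 of 28 higher, percentile 96.5, or 16 of 26 without *GCD10* and *GCD14*), and *PAB1* among them was 3.97-fold lower in the authors' deposited table. Of the elongation and termination list, with a median of -0.35 (percentile 7.0), the elongation factor *YEF3* was 3.52-fold lower in the authors' deposited table. TE medians of the other lists at 15 °C were -0.18 for cytosolic ribosomal proteins (percentile 17.0, or 0.0 with length matched), 0.01 for mitochondrial ribosomal proteins, -0.24 for glycolysis and fermentation, -0.15 for heat shock proteins and chaperones, 0.06 for cold-induced genes, -0.10 for the general stress response, -0.23 for amino acid synthesis, 0.03 for oxidative phosphorylation, -0.10 for the cell wall, 0.01 for mRNAs with upstream open reading frames, 0.42 for sporulation and -0.31 for strain markers.

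The mRNA levels at 15 °C were at least 1.5-fold higher in *tif3*Δ for 340 of 5015 genes and lower for 293. Cytosolic ribosomal protein genes were higher in 134 of 135 cases (*RPP1* left out), with a median of 0.60 (percentile 100.0, the same with length matched), and the list had a footprint median of 0.41 (124 of 136 higher, percentile 99.9, but inside the middle 95% with length matched). The highest and lowest mRNA differences named here are among genes with a mean normalised value of 32 or more in both library types. Highest in the authors' deposited table were *ARO10* (6.35-fold) and *ARO9* (3.40-fold) of aromatic amino acid breakdown, and *SNZ1* of vitamin B6 synthesis (5.31-fold). The authors' deposited table also put the oxidoreductase *OYE3* (5.02-fold), YCR102C (4.59-fold), *HSP30* (4.27-fold), YLR460C (4.13-fold) and *NCA3* (3.27-fold) among the highest. The authors' deposited table listed *HO* (5.86-fold), *SAM2* (3.86-fold), *FPT1* (3.47-fold), *MXR1* (3.06-fold), *SFG1* (2.89-fold), *MET6* (2.81-fold), *MCD1* (2.52-fold) and *ACM1* (2.51-fold) as lowest. Footprints were at least 1.5-fold higher for 801 genes and lower for 1036. Footprint differences were likewise ranked among genes with a mean of 32 or more in both library types. The highest in the authors' deposited table were *FLR1* (21.4-fold), YNL042W-B (11.6-fold), *SNZ1* (9.24-fold), YCR102C (8.95-fold) and YLR460C (8.16-fold). The lowest in the authors' deposited table were *LAM6* (8.06-fold lower), *SAM35* (6.85-fold), *SLF1* (6.52-fold), *MMS1* (6.45-fold) and *KRE5* (6.41-fold).

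Predicted folding of the region around the start codon was compared with the TE difference, using the 60 nt before and the 15 nt from the start codon. This stretch was taken from the genome without regard to transcription starts or introns. It may therefore hold sequence that is not in the mRNA, and is only a rough measure of 5′ leader structure. The 10% of genes with the strongest folding had lower TE in *tif3*Δ at both temperatures, with medians of -0.09 at 37 °C and -0.29 at 15 °C, each at percentile 0.0 with and without length matching. At 37 °C their footprint median was -0.01 (percentile 2.3, or 15.6 with length matched) and their mRNA median 0.06 (percentile 99.9, or 97.9 with length matched). At 15 °C their footprint median was -0.33 (percentile 0.0) and their mRNA median 0.00 (percentile 84.4, or 97.6 with length matched). The 10% with the weakest folding had medians of 0.13 and 0.11 (percentile 100.0 at both temperatures, but outside the middle 95% with length matched at 15 °C and not at 37 °C). Across genes the correlation of the TE difference with folding energy was 0.125 at 37 °C and 0.209 at 15 °C. The 10% with the highest wild-type TE, as measured at the other temperature, had TE medians of -0.13 at 37 °C and -0.17 at 15 °C (percentiles 0.0 and 0.3), and the 10% with the lowest -0.04 and 0.05 (percentiles 0.0 and 37.5, or 68.4 and 49.7 with length matched). For the 10% with the most wild-type mRNA at the other temperature the TE medians were 0.07 and -0.17, and for the 10% with the least 0.29 and 0.14. The shortest 10% had 0.51 and 0.07, and the longest 10% -0.55 and -0.01.

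The experiments share no libraries, so the overlap between them was counted. Of 4999 genes measured in both, 236 had TE at least 1.5-fold lower in both, against 104.2 for independent lists, and 136 at least 1.5-fold higher in both, against 64.1. The TE differences correlated across genes with Pearson r = 0.321 and Spearman rho = 0.328, mRNA differences with rho = 0.148 and footprint differences with rho = 0.355. Of the 10 named genes lowest in TE at 37 °C, *MMS1*, *PCL5*, *URA2*, *ADH4*, *PEP1* and *DUR1,2* were also lower at 15 °C, by 6.85-fold to 1.75-fold in the authors' deposited table. Of these, *PCL5*, *ADH4*, *MMS1* and *DUR1,2* had only about 5, 9, 9 and 17 *tif3*Δ footprints at 15 °C. In the authors' deposited table *HER1* and *ODC2* were 1.27-fold and 1.19-fold lower at 15 °C, *HBT1* 1.04-fold higher and *ATF1* 2.04-fold higher. For 1685 genes the TE differences at the 2 temperatures were at least 1.5-fold apart. None of these was tested, and the experiments also appear to differ in mating type.

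**Figure D4:**
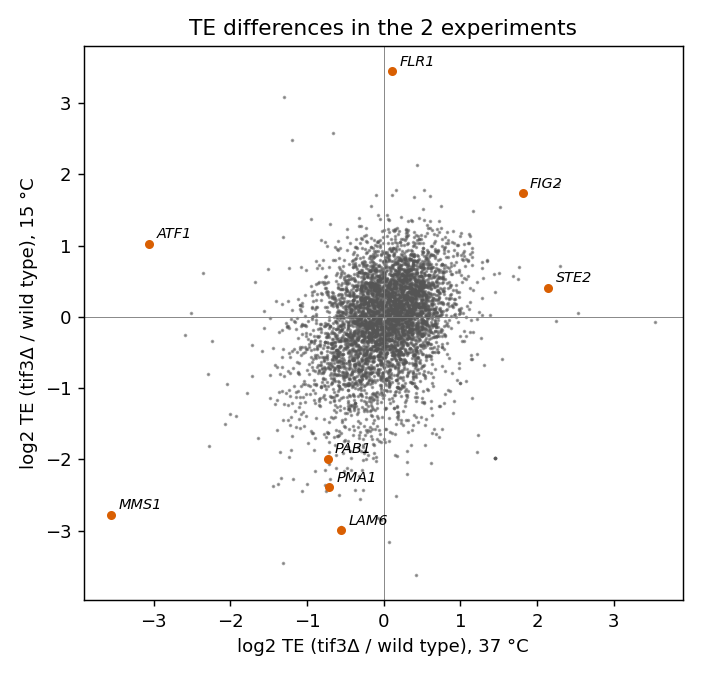
Log2 TE difference of *tif3*Δ over wild type at 37 °C (x axis) and 15 °C (y axis); each point is 1 gene, of 4999 measured in both, and 8 named genes are marked. The Spearman correlation is 0.328, and *MMS1* lies lowest at 37 °C.

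In wild type, the 37 °C and 15 °C groups differ in temperature and experiment and, by the mRNAs below, apparently in mating type, which cannot be told apart. The tables were normalised separately, so values are relative to the median gene. TE differed by at least 1.5-fold for 1586 of 4999 genes, and wild-type TE correlated between the experiments with rho = 0.753. Heat shock and chaperone genes had 1.61-fold higher TE at 37 °C (28 of 36, percentile 100.0), glycolysis genes 1.87-fold higher (18 of 18, percentile 100.0) and cold-induced genes also 1.61-fold higher (9 of 12, percentile 99.4). Footprints at 37 °C were 1.32-fold higher for heat shock and chaperone genes (24 of 36, percentile 100.0) and 1.13-fold higher for glycolysis genes (12 of 18, percentile 98.3). The cold-induced genes instead had 1.65-fold more footprints at 15 °C (10 of 12, percentile 0.0). The mRNA of heat shock and chaperone genes was 1.32-fold higher at 15 °C (22 of 36, percentile 54.8) and that of glycolysis genes 1.87-fold higher at 15 °C (18 of 18, percentile 0.3). The cold-induced genes had 2.46-fold more mRNA at 15 °C (10 of 12, percentile 0.0), among them the fatty acid desaturase *OLE1* with 11.3-fold and *NSR1* with 4.92-fold more. The 6 a-specific genes measured in both had less mRNA in wild type at 37 °C than at 15 °C, with a median log2 difference of -5.00, and mRNA of the α-specific *SAG1* stood at 1.7 relative to the median gene at 37 °C and at -1.4 at 15 °C. *URA3* and *MET17*, used as strain markers, were listed at 15 °C and not at 37 °C, and at 15 °C the authors' deposited table put their mRNA 2.35-fold and 2.18-fold lower in *tif3*Δ. The labels give the same strain names in both experiments.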

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

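The 2-fold size, the omission of mating and histone genes, length matching, lists without members of other function, the relations given GC content or mRNA level and the unfiltered agreement were chosen after seeing the data. No paired analysis was possible because the tables hold 1 value per group and no replicate columns. For the same reason the planned RLE size factors, TMM within each library type, DESeq2 and voom tests, adjusted p of 0.10, replicate and culture blocks, spread shared by all 16 libraries, fry, estimated correlation and leave-one-out fits were not run. Of 54 alternatives, 42 stayed within 1.5 times the count or 0.1 of the correlation, and no correlation turned its sign. With a filter of 64 the genes at least 1.5-fold apart at 15 °C numbered 1074 for TE and 391 for mRNA. At that filter 1094 differed in TE between temperatures and 1045 in wild-type TE. Fewer genes are counted then, but the share also fell, for TE at 15 °C from 1641 of 5012 to 1074 of 3746. A size of 2-fold gave 278 genes for TE, 305 for mRNA and 481 for footprints at 37 °C, 550, 124 and 674 at 15 °C, 615 for the difference between temperatures and 479 for wild type, since the size is stricter. At 2-fold, 151 genes were higher and 399 lower in TE at 15 °C, and 204 higher and 470 lower in footprints, so the share of lower genes was larger than at 1.5-fold. For TE at 37 °C 122 were higher and 156 lower, for footprints 231 and 250. For mRNA 159 were higher and 146 lower at 37 °C, where slightly more were lower at 1.5-fold, and 69 and 55 at 15 °C. Leaving out list members of other function changed no number of lists outside the middle 95% with expression matched. With length matched too, the proteasome list in mRNA at 37 °C moved from percentile 5.4 to 1.9, and the mitochondrial ribosomal proteins in mRNA at 15 °C from 1.9 to 3.3. The correlation of TE with coding length at 37 °C ran from -0.609 given mRNA level to -0.687 with the filter of 64, and at 15 °C from -0.049 to -0.134. Matching on length took the ribosomal protein and oxidative phosphorylation lists at 37 °C back inside the middle 95% for TE and put the cell wall list and the mRNAs with upstream open reading frames outside it; at 15 °C it put the ribosomal protein list outside. Depth also limits the 15 °C values: a normalised value of 32 stands for about 15 footprints in *tif3*Δ and 44 in wild type.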

Other observations

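The tests of the mating-type and length patterns below, and the lists of histone, branched-chain, haploid-specific and membrane protein genes, were chosen after the results were seen, and the histone test below replaced a first test on the a-specific genes, which are part of the pattern; the test of the spread at 15 °C was written before its result was seen. At 37 °C all 10 histone genes had less mRNA in *tif3*Δ (median log2 difference -1.81, 3.51-fold), while at 15 °C their median was 0.14. Their TE was higher in 10 of 10 cases at both temperatures, with medians of 0.36 and 0.49, but among random lists matched on coding length these stood at percentiles 2.4 and 99.9. The 6 genes of branched-chain amino acid synthesis and transport tied to the regulator Leu3 had more mRNA at both temperatures, with medians of 1.87 at 37 °C and 0.69 at 15 °C. In the authors' deposited table *OAC1*, a mitochondrial carrier, was 6.90-fold higher and the aminotransferase *BAT1* 5.91-fold higher at 37 °C. *MET6*, methionine synthase, went opposite ways in the authors' deposited table, with mRNA 2.69-fold higher at 37 °C and 2.81-fold lower at 15 °C.

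Genes encoding proteins with 4 or more hydrophobic segments, a rough mark of membrane proteins, had lower TE in *tif3*Δ at both temperatures. The median was -0.25 at 37 °C (204 of 287 lower) and -0.30 at 15 °C (182 of 269 lower), at percentiles 0.3 and 0.0 of random lists matched on expression and coding length. *MMS1*, next to *TIF3*, had 2.47-fold higher mRNA at 37 °C and 1.06-fold higher mRNA at 15 °C in the authors' deposited table, and its TE, among genes with a mean of 32 or more, was among the 3 lowest at both temperatures.

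Transcripts of a cells, of α cells and of the pheromone response were higher together in *tif3*Δ at 37 °C, where in wild type the 7 a-specific genes lay below the median gene and 3 of the 4 α-specific genes above it. RNA of a cells carried into these libraries would not by itself account for the α-specific mRNA, whose median was 2.92 higher. That rise is part of the pattern itself, so it is no separate test. Both mating types expressed within every cell would lower the genes that a/α cells repress, whose median was 0.65 higher (10 of 11 genes, *HO* being lower). A rise of pheromone-response mRNAs with eIF4B loss at any temperature would also be seen at 15 °C, where their mRNA median was 0.09. Their footprint median there was 0.51, however (18 of 23 higher, percentile 100.0). The cells at 15 °C also appear to be of another mating type, so the 15 °C values cannot decide this. A candidate explanation is that a cells were present among α cells in the *tif3*Δ cultures, so that each answered the other and stopped before S phase. The histone median of -1.81 goes with this, but would go with any pheromone signal. An effect of eIF4B loss, at 37 °C alone or at both temperatures, stays open. The group values do not show whether 1 or both libraries carried these transcripts. At 15 °C both genotypes had a-specific mRNA. The α-specific *SAG1* and *STE3* stood at 1.7 and 1.1 relative to the median gene in wild type at 37 °C, and at -1.4 and -3.0 at 15 °C. The a-specific genes went the other way, with a median log2 difference of -5.00 (37 °C minus 15 °C). These values argue against wild-type cells of 1 mating type in both experiments, so mating type goes with temperature.

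The TE difference was lower for longer genes at 37 °C and hardly so at 15 °C. A length trend of the mRNA libraries alone would leave footprints unrelated to length at 37 °C, but their correlation was -0.322. GC content of the coding sequence correlated with the mRNA difference at 15 °C (rho = 0.365), yet the relation of TE with length given GC content was -0.134 there, which argues against GC content hiding a relation as strong as at 37 °C. The footprint trends had one sign at both temperatures and the mRNA trends opposite signs, which may mean that the contrast between temperatures lies on the mRNA side. A length trend in both library types and an effect of eIF4B on long mRNAs stay open, the latter untested. At 37 °C the *tif3*Δ groups also carried the mating-type and pheromone pattern, so no difference there can be told apart from that state. Leaving out the pheromone, mating-type and histone genes kept the correlation at -0.653, but this does not remove indirect effects of that state.

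TE differences spread more widely at 15 °C (interquartile range 0.81) than at 37 °C (0.64). Over 317 genes with a mean worth at least 1000 *tif3*Δ footprints at both temperatures the ranges were 0.50 and 0.69, a ratio of 0.72. The standard deviations of these genes were 0.45 at 15 °C and 0.49 at 37 °C, so the wider spread at 15 °C was not seen among them. Counting noise of the shallower *tif3*Δ footprints could give this. These deep genes are a different set, however, with a wider range at 37 °C than all genes, so the comparison does not isolate counting noise. Whether the larger number of genes at least 1.5-fold apart at 15 °C reflects larger effects stays open, and a biological source was not tested. Deep genes such as *PMA1* and *YEF3* still stood far apart at 15 °C.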
